A study of Mus musculus with 39 samples.

How the data were processed

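Total RNA from HL-1 cells and from isolated neonatal mouse cardiomyocytes (NNC) was amplified, labelled with biotin and hybridised to mouse Illumina whole-genome BeadChips, per the labels' protocols. The 39 arrays used here form 10 groups, named in the labels by cell model, stimulus, hours and replicate number: control serum (CON), infectious serum (PCI), control serum with LPS, and control serum with the cytokine mix CM, each at 6 h and 12 h in NNC, and CON and PCI at 6 h in HL-1. Each group held 4 arrays, except LPS at 12 h, where 3 were used and any other was not analysed here.

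The deposited table of probes holds, per the file headers, a signal and a detection p-value for each probe and array. The deposited signal is an intensity on a linear scale, from 82.8 upwards, not normalised, with no negative values. GenomeStudio 1.9.0 and lumi are named in the submitters' processing notes; which steps each was used for is not given in the sources used here. A second deposited table holds processed log2 values. Its scale was read from the values: array medians lay between 7.64 and 7.68, and each array correlated with the log2 of its own deposited signal at r = 0.9975 or more. How the authors transformed and normalised these log2 values is not given in the sources used here.

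Probes were named by the gene symbol in the deposited annotation. Of 25697 probes, 23978 had 1 symbol, 0 had several and 1719 had none, which gave 16593 genes. By Entrez ID, 23962 probes matched a current gene table, and 0 of their symbols differed. Each gene was represented by the probe with the highest mean over all 39 arrays. Other detected probes of the genes named in the text changed with the same sign wherever the gene passed its test.

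The work was done in R 4.3.3 with limma 3.58.1. Signals were background corrected with the normal-exponential model of limma's neqc, with the background taken from the detection p-values, an offset of 16 was added, and values were put on the log2 scale and quantile normalised over all arrays. A gene was tested when its probe was detected at a p under 0.01 on at least 3 arrays of the fit. Group means were fitted by linear models, differences were tested with limma's moderated statistics, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with an adjusted p under 0.05 as the threshold. NNC comparisons took their spread from all 31 NNC arrays, HL-1 comparisons from the 8 HL-1 arrays, and comparisons between the models from the 16 arrays with CON or PCI at 6 h. Differences between responses (between models or times) were tested as interaction terms. Changes of a gene detected on no array of 1 group are given with the lowest fold that the detection limit allows, except in interaction terms, for which no bound was computed. Adding 16 to each signal shrinks the changes of dim genes.

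The comparisons, the choice of tests, 41 gene lists (pathways, cell type markers and complexes), the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 8 largest significant changes per direction against control and the 5 largest in other comparisons, among genes detected on every array of at least 1 of the groups, up to 4 members per list with the smallest p, and 18 genes fixed in advance. The text prints part of these, chosen by list, and mostly leaves out genes that lost their call when 1 array was left out. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists with at least 5 measured members. Members were counted as higher or lower after adjustment over all genes, and again after adjustment over the list alone. A second p came from camera with the correlation between genes estimated for each list, and limma's fry asked whether the members moved at all rather than more than other genes. The overlap expected of independent lists is the product of the call counts divided by the genes tested in both. Responses that share control arrays were compared with separate controls on each side, 2 of the 4, averaged over all splits, and beside simulated groups without any change.

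All arrays were kept. The share of probes detected measures signal over background, and was 37.99 % to 42.2 % on each array. The replicate numbers pair arrays in 2 settings. Deviations from the group means of equally numbered HL-1 arrays with CON and PCI correlated at 0.146 to 0.694 over 4 pairs, and 3 of 4 arrays correlated best with their own number. In NNC, arrays of the same stimulus and number at 6 h and 12 h correlated at 0.420 to 0.807. All 15 correlated best with their own number. The pairing comes from the data, as the labels name no shared cultures or days. The NNC fit ignored it, so p-values may be too small between stimuli and too large between times.

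The steps were tested on simulated data made from the means and spreads of the real arrays, with known changes in some genes. For PCI in NNC at 6 h (8257 genes, 31 arrays), 38.8 % of genes changed 1.5-fold, 88.1 % of those changed 2-fold and 97.0 % of those changed 4-fold were called, and 8 of 8042 unchanged genes. For PCI in HL-1 (7409 genes, 8 arrays) these were 40.3 %, 76.1 % and 98.5 %, and 8 of 7196. For the difference between the models (8480 genes, 16 arrays) they were 11.9 %, 46.3 % and 90.9 %, and 5 of 8267. For the difference between PCI responses at 12 h and 6 h (8257 genes, 31 arrays) they were 20.9 %, 49.3 % and 84.8 %, and 4 of 8042. No called change had the wrong sign. A gene list shifted by 0.5 on the log2 scale was called in each of the 4 simulations, beside 0 of 36, 0 of 30, 0 of 36 and 1 of 36 other lists. The simulated noise was independent for each gene and array, without correlation between genes or between arrays of 1 culture. The low numbers of false calls therefore do not carry over to the real arrays, least of all for gene lists.

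The alternatives, whose effect the closing section gives, were the deposited log2 table, no background correction, median scaling in place of quantile normalisation, normalisation of each cell model apart, no filter on dim probes, detection on at least 0.5 of the arrays, every named probe counted on its own, limma's array weights, the arrays compared alone in the fit, all 39 arrays in a fit, a required change of 2-fold, the replicate number as a block, and each array left out in turn. For gene lists they were the estimated correlation and fry, and for similarity the same controls on both sides. After the data were seen, 3 more were added: removal of the NNC cultures that lie apart from the others, the NNC culture as a block, and, for PCI in NNC at 6 h, the arrays compared alone on the genes of the full fit. A planned block by slide was not run, because no slide is named in the files used here. Splits of the arrays into other groups of the same sizes were counted, all 35 for a pair of groups and 100 drawn for differences between responses.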

Results

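Gene expression was measured on mouse whole-genome Illumina BeadChips in a pair of heart muscle cell models. HL-1 is an immortalised mouse line derived from atrial cardiomyocytes, and NNC are cardiomyocytes freshly isolated from newborn mouse hearts, a preparation that also holds other heart cells. Cells were kept for 6 or 12 h in serum-free medium with 5 % mouse control serum, with 5 % infectious mouse serum (PCI in the labels), with control serum and 200 ng/ml LPS, or with control serum and a cytokine mix, CM. The CM contained, in ng/ml, TNF-α and IL-6 at 50 each, IL-1β and IFN-γ at 10 each, and LPS at 100. NNC received all 4 media at both times, and HL-1 received control and PCI serum for 6 h.

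The 39 arrays comprised 31 of NNC in 8 groups and 8 of HL-1 in 2 groups. Each group had 4 arrays except NNC with LPS for 12 h, which had 3. Median deposited signals per array lay between 151.5 and 279.4, and 37.99 % to 42.2 % of the 25697 probes were detected. No pair of arrays held identical values. The labels do not say that replicates were separate cell preparations, so the p-values may reflect technical as well as biological spread. Values are normalised log2 intensities and changes are log2 differences, each with its standard error (SE) from limma. For a gene that was detected on no array of 1 group, the log2 difference is uncertain in size, and a fold written as at least so much is a lower bound. This bound sets the mean of the bright group against the dim group's mean of, per array, the higher of the lowest detected value and the probe's own value. Differences between responses carry no such bound, and those of genes undetected in a group, such as Slc10a6, are uncertain in size. For every gene named below as higher or lower against control, each stimulated array lay beyond each control array.

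**Figure D1:**
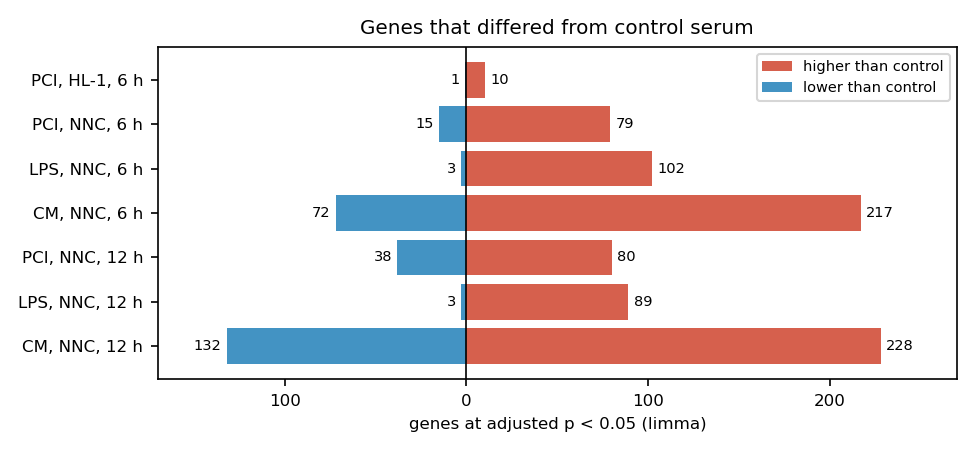
Numbers of genes higher (right) and lower (left) than control serum at an adjusted p under 0.05 in limma, for each stimulus, cell model and time. CM moved the most genes, 360 at 12 h, and PCI in HL-1 the fewest, 11.

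The first question was how NNC respond to infectious serum. After 6 h the largest increase was in Slc10a6, a transporter of sulfated steroid hormones, whose log2 intensity rose by 4.62 (SE 0.22), at least 11.8-fold (n = 4 arrays per group, adjusted p = 6.0e-14). Usp18, which removes the ubiquitin-like protein ISG15 and damps interferon signalling, rose by 2.76 (SE 0.28). The secreted acute phase proteins Lcn2 and Serpina3n rose by 2.66 (SE 0.36) and 2.48 (SE 0.23). Fkbp5, a co-chaperone of the glucocorticoid receptor that is itself induced by glucocorticoids, rose by 1.65 (SE 0.15). Il11, a cytokine of the interleukin-6 family, fell, at -1.56 (SE 0.32), and so did Ky, a muscle protein, at -1.43 (SE 0.26, at least 1.91-fold).

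Glucocorticoid-induced genes rose together at 6 h. Of 21 measured members, 6 rose, 0 fell and 15 did not pass the test (10 higher and 0 lower adjusted over the list alone). The list's median change was 0.45 (adjusted p = 1.7e-15, and adjusted p = 1.4e-05 with an estimated correlation). Beside Lcn2 and Fkbp5, these were Mt2, a metal-binding metallothionein, at 1.75 (SE 0.31), Pdk4, which inhibits pyruvate dehydrogenase, at 1.09 (SE 0.13), the transcription factor Klf9 at 0.82 (SE 0.11), and the clock gene Per1. Of 28 type I interferon-stimulated genes, 7 rose, 0 fell and 21 did not pass the test (16 higher and 0 lower adjusted over the list alone), among them Irf9, a subunit of the interferon-activated transcription factor ISGF3, at 1.54 (SE 0.15), and Isg15 at 1.61 (SE 0.27). Their median change was 0.75 (adjusted p = 2.4e-25, and adjusted p = 0.064 with an estimated correlation). Of 13 interferon-gamma-induced GTPases and regulators, 4 rose, 0 fell and 9 did not pass the test (5 higher and 0 lower adjusted over the list alone), with a median of 0.23 (adjusted p = 4.1e-06, and adjusted p = 0.32 with an estimated correlation). Of 19 acute phase and IL-6/STAT3 targets, 5 rose, 0 fell and 14 did not pass the test (7 higher and 0 lower adjusted over the list alone), including the pentraxin Ptx3 at 1.56 (SE 0.30) and the ferroxidase Cp at 1.24 (SE 0.25) (list median 0.40, adjusted p = 5.4e-11, and adjusted p = 0.082 with an estimated correlation).

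The inflammatory mediators Il6, Ccl2, Cxcl1 and Cxcl10 did not pass the test with PCI at 6 h, at 0.19 (SE 0.44), 0.10 (SE 0.22), 0.30 (SE 0.16) and -0.13 (SE 0.23). Cxcl10 was detected on none of these arrays, and the Cxcl1 probe was close to the scanner's maximum, where changes are compressed. Of 25 cytokines and chemokines, 0 rose, 1 fell and 24 did not pass the test (3 higher and 2 lower adjusted over the list alone). Cholesterol biosynthesis genes had a median of -0.39 with none of 17 past the test (adjusted p = 6.4e-05, and adjusted p = 0.55 with an estimated correlation). In limma, 94 of 8257 genes passed, 79 higher and 15 lower. With only these 8 arrays in the fit, 12 genes passed, and Il11, Ky, Isg15, Klf9, Per1, Ptx3 and Cp were no longer among them. Per1 (0.90 (SE 0.20), adjusted p = 0.016) also lost its call without control replicate 2 (adjusted p = 0.082) or 3 (0.075) or without PCI replicate 2 (0.07) or 4 (0.056).

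**Figure D2:**
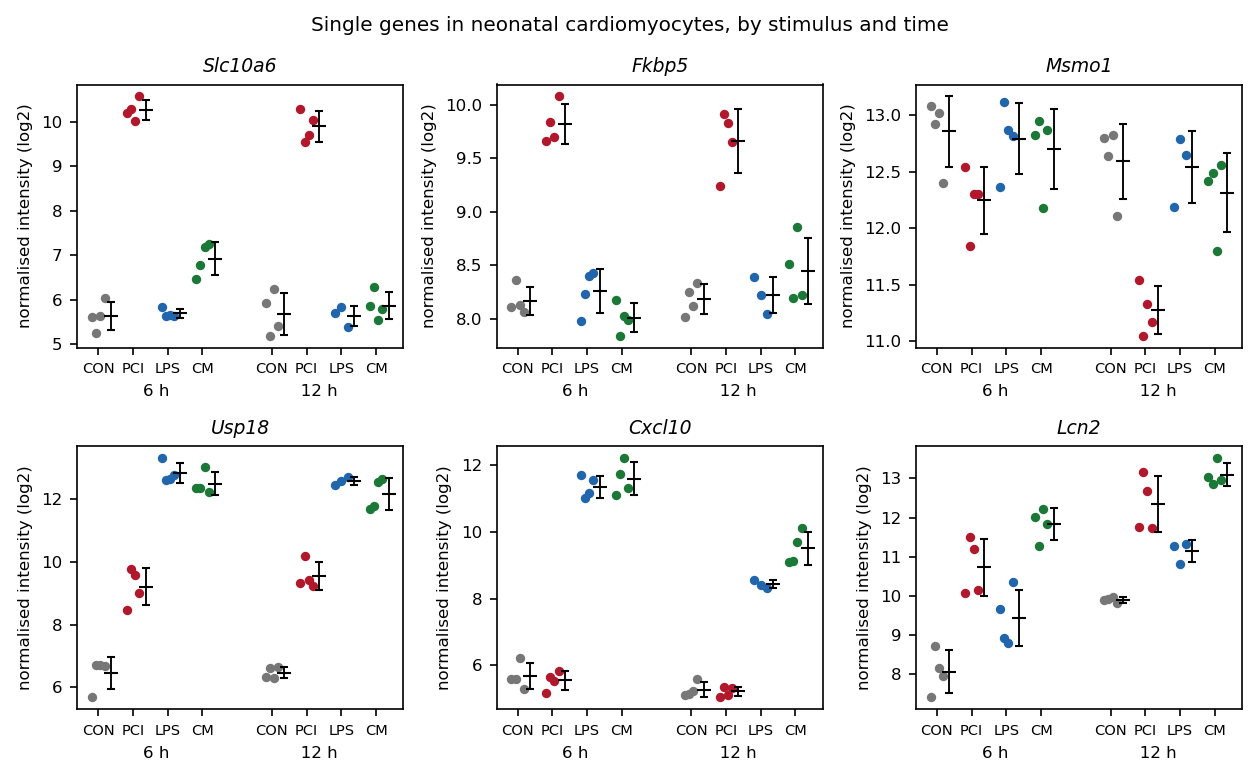
Normalised intensity (log2) of 6 genes on each NNC array, as points, with the mean and SD of each group beside them (n = 4 arrays, 3 for LPS at 12 h), by stimulus and time (CON, control serum). Slc10a6 at 6 h had a mean of 10.26 with PCI and 5.69 with LPS, and Cxcl10 means of 5.55 and 11.35.

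The same comparison after 12 h asked whether the response to PCI serum lasts. Slc10a6 was again higher, by 4.2 (SE 0.22), at least 9.04-fold (n = 4 per group, adjusted p = 6.1e-13). Usp18 rose by 3.08 (SE 0.28), Isg15 by 2.38 (SE 0.27), Lcn2 by 2.44 (SE 0.36), Serpina3n by 2.35 (SE 0.23), Ptx3 by 1.99 (SE 0.30) and Fkbp5 by 1.47 (SE 0.15). Cholesterol biosynthesis genes fell together. Of 17 measured members, 0 rose, 5 fell and 12 did not pass the test (0 higher and 13 lower adjusted over the list alone), with a median of -0.83 (adjusted p = 3.2e-18, and adjusted p = 0.039 with an estimated correlation). Msmo1, an enzyme of the demethylation steps after lanosterol, was at -1.32 (SE 0.21). Ky was at -1.99 (SE 0.26), and Tnfrsf11b, the decoy receptor osteoprotegerin, at -1.69 (SE 0.33).

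Of 21 glucocorticoid-induced genes at 12 h, 7 rose, 0 fell and 14 did not pass the test (9 higher and 0 lower adjusted over the list alone), with a median of 0.54 (adjusted p = 5.3e-16, and adjusted p = 1.2e-05 with an estimated correlation). Pdk4 was higher by 0.99 (SE 0.13) and the sulfotransferase Sult1a1 by 1.79 (SE 0.27, at least 1.33-fold). Of 28 type I interferon-stimulated genes, 10 rose, 0 fell and 18 did not pass the test (22 higher and 0 lower adjusted over the list alone), with a median of 0.90 (adjusted p = 4.8e-32, and adjusted p = 0.024 with an estimated correlation). Of 19 acute phase and IL-6/STAT3 targets, 4 rose, 0 fell and 15 did not pass the test (5 higher and 0 lower adjusted over the list alone), with a median of 0.51 (adjusted p = 6.5e-12, and adjusted p = 0.048 with an estimated correlation). The interferon-gamma-induced GTPases, with Gbp3 at 2.03 (SE 0.32), had a median of 0.32 with 3 of 13 higher (adjusted p = 2.9e-06, and adjusted p = 0.18 with an estimated correlation). Cd14, the co-receptor for LPS, rose by 0.98 (SE 0.13). Il6 and Cxcl10 did not pass, at -0.04 (SE 0.44) and -0.05 (SE 0.23), and Cxcl10 was again detected on none of the arrays. Macrophage and leukocyte markers had a median of 0.10 and did not pass (adjusted p = 0.24, and adjusted p = 0.79 with an estimated correlation).

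In limma, 118 genes differed after 12 h of PCI serum, 80 higher and 38 lower. Of the genes higher at 6 h, 53 were also among those higher at 12 h, where independent lists would share 0.765, and 9 were lower at both times (independent lists 0.0690). The 6 h and 12 h changes, which share no arrays, correlated across 8257 genes at r = 0.662. Arrays of the same stimulus and number deviated together at both times, so part of this correlation and of these overlaps may come from shared cultures, here and for LPS and CM below. With only these 8 arrays in the fit, 39 genes passed.

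LPS was given to NNC to separate the effect of this bacterial product from that of infectious serum. After 6 h, Rsad2, an antiviral enzyme, rose by 6.76 (SE 0.27), at least 55.3-fold (n = 4 per group, adjusted p = 4.9e-16). The chemokine Cxcl10 rose by 5.67 (SE 0.23), at least 25.1-fold, and the cytokine Il1b by 5.56 (SE 0.14), at least 20.6-fold. Ifit3 rose by 5.79 (SE 0.38) and Isg15 by 4.66 (SE 0.27). Cd14 and Tlr2, receptors for bacterial products, rose by 1.69 (SE 0.13) and 1.76 (SE 0.17).

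Of 28 type I interferon-stimulated genes, 25 rose, 0 fell and 3 did not pass the test (27 higher and 0 lower adjusted over the list alone), with a median of 2.66 (adjusted p = 2.7e-179, and adjusted p = 2.5e-07 with an estimated correlation). Of 13 interferon-gamma-induced GTPases and regulators, 8 rose, 0 fell and 5 did not pass the test (11 higher and 0 lower adjusted over the list alone), among them Igtp at 4.65 (SE 0.32) and Gbp2 at 3.85 (SE 0.37) (list median 1.33, adjusted p = 7.3e-48, and adjusted p = 1.8e-05 with an estimated correlation). Of 25 cytokines and chemokines, 9 rose, 0 fell and 16 did not pass the test (13 higher and 0 lower adjusted over the list alone), including Ccl3 at 3.88 (SE 0.25, at least 6.90-fold) (median 0.90, adjusted p = 1.3e-46, and adjusted p = 4.7e-05 with an estimated correlation). Of 16 genes of MHC class I antigen presentation, 4 rose, 0 fell and 12 did not pass the test (7 higher and 0 lower adjusted over the list alone), with the immunoproteasome subunit Psmb9 at 1.88 (SE 0.17, at least 2.44-fold) and the peptide transporter Tap1 at 1.75 (SE 0.24, at least 1.57-fold) (median 0.47, adjusted p = 9.3e-17, and adjusted p = 8.0e-04 with an estimated correlation). Inducible mediator and oxidative enzymes, led by the prostaglandin synthase Ptges at 1.18 (SE 0.19, at least 1.82-fold), had a median of 0.17 with 2 of 14 higher (adjusted p = 7.3e-05, and adjusted p = 0.04 with an estimated correlation). Casp1, the protease that activates IL-1β, rose by 2.31 (SE 0.23, at least 3.29-fold).

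Several mediators that were already bright in control serum did not pass with LPS at 6 h. Il6 changed by 0.46 (SE 0.44) from a control mean of 12.21, Ccl2 by 0.38 (SE 0.22) from 13.81, and Cxcl1 by 0.25 (SE 0.16) from 15.26. Lcn2 was at 1.36 (SE 0.36) and Fkbp5 at 0.09 (SE 0.15), neither past the test. Glucocorticoid-induced genes had a median of 0.02, with 0 of 21 higher (adjusted p = 0.94, and adjusted p = 0.98 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.25, with none of 18 past the test alone (adjusted p = 0.0081, and adjusted p = 0.61 with an estimated correlation), and the list did not pass without control replicate 2 (adjusted p = 0.18) or 4 (0.06), without LPS replicate 3 (0.14) or without a filter on dim probes (0.068). In limma, 105 genes passed, 102 higher and 3 lower.

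At 12 h, LPS kept many of these transcripts high. Il1b was higher by 5.83 (SE 0.15), at least 21.8-fold (n = 3 LPS and 4 control arrays, adjusted p = 2.7e-20), Usp18 by 6.13 (SE 0.31), Ifit3 by 5.35 (SE 0.41), Isg15 by 5.01 (SE 0.29), Il1a by 3.74 (SE 0.27, at least 5.91-fold) and Ccl3 by 3.09 (SE 0.27). Cxcl10 was higher by 3.16 (SE 0.25, at least 3.27-fold) and Cd14 by 2.66 (SE 0.14). Of 28 type I interferon-stimulated genes, 24 rose, 0 fell and 4 did not pass the test (26 higher and 0 lower adjusted over the list alone) (median 2.35, adjusted p = 1.2e-160, and adjusted p = 7.0e-07 with an estimated correlation). Of 25 cytokines and chemokines, 10 rose, 0 fell and 15 did not pass the test (15 higher and 0 lower adjusted over the list alone) (median 0.81, adjusted p = 6.0e-53, and adjusted p = 2.6e-05 with an estimated correlation). Of 16 class I antigen presentation genes, 3 rose, 0 fell and 13 did not pass the test (9 higher and 0 lower adjusted over the list alone), with Psmb9 at 1.74 (SE 0.18, at least 2.47-fold) (median 0.75, adjusted p = 5.4e-21, and adjusted p = 2.5e-04 with an estimated correlation). The GTPase list had a median of 1.08 (adjusted p = 3.0e-30, and adjusted p = 2.5e-04 with an estimated correlation) and the mediator enzymes one of 0.22 (adjusted p = 2.8e-07, and adjusted p = 0.0079 with an estimated correlation). Macrophage and leukocyte markers had a median of -0.36, with 1 of 18 higher and 2 lower (adjusted p = 0.0029, and adjusted p = 0.39 with an estimated correlation). The NF-κB pathway list passed as higher with LPS at both times, but not with an estimated correlation. In limma, 92 genes passed at 12 h, 89 higher and 3 lower, and 79 genes were higher at both times (independent lists 1.10). The changes at 6 h and 12 h correlated across genes at r = 0.779.

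CM combined recombinant cytokines with LPS at 100 ng/ml, below the 200 ng/ml given alone. After 6 h Rsad2 rose by 6.56 (SE 0.27), at least 48.2-fold, Il1b by 6.04 (SE 0.14), at least 28.8-fold, and Cxcl10 by 5.91 (SE 0.23), at least 29.6-fold (n = 4 per group, adjusted p = 6.9e-16, 1.6e-21 and 4.2e-16). Lcn2 rose by 3.76 (SE 0.36), Ptges by 2.50 (SE 0.19, at least 4.54-fold), Tlr2 by 3.19 (SE 0.17) and Hamp, which encodes the iron hormone hepcidin, by 2.26 (SE 0.17, at least 1.58-fold). The matrix proteases Mmp3 and Mmp13 rose by 2.35 (SE 0.33) and 3.54 (SE 0.74), and Slc7a11, which imports cystine for glutathione synthesis, by 2.09 (SE 0.22, at least 3.41-fold). Among the genes that fell were the ligand gene Tnfsf18 at -1.97 (SE 0.40) and the growth factors Tgfb3 at -1.43 (SE 0.30) and Bmp4 at -1.36 (SE 0.24). Others were Fst, which binds activin, at -1.28 (SE 0.24), Medag at -1.79 (SE 0.22) and Fam180a at -1.89 (SE 0.36).

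Of 25 cytokines and chemokines, 15 rose, 0 fell and 10 did not pass the test (21 higher and 0 lower adjusted over the list alone) (median 1.38, adjusted p = 7.8e-45, and adjusted p = 9.1e-05 with an estimated correlation). Of 23 NF-κB pathway and feedback genes, 6 rose, 0 fell and 17 did not pass the test (16 higher and 0 lower adjusted over the list alone), with the feedback regulators Zc3h12a at 1.06 (SE 0.17) and Tnip1 at 1.31 (SE 0.21) (median 0.60, adjusted p = 1.0e-13, and adjusted p = 0.021 with an estimated correlation). Of 28 type I interferon-stimulated genes, 25 rose, 0 fell and 3 did not pass the test (27 higher and 0 lower adjusted over the list alone) (median 2.45, adjusted p = 1.6e-92, and adjusted p = 7.4e-05 with an estimated correlation). Of 19 acute phase and IL-6/STAT3 targets, 8 rose, 0 fell and 11 did not pass the test (11 higher and 0 lower adjusted over the list alone) (median 0.65, adjusted p = 3.8e-14, and adjusted p = 0.016 with an estimated correlation). Of 14 mediator and oxidative enzymes, 6 rose, 0 fell and 8 did not pass the test (8 higher and 0 lower adjusted over the list alone) (median 0.52, adjusted p = 5.0e-09, and adjusted p = 0.0028 with an estimated correlation). The GTPase list had a median of 1.81 (adjusted p = 2.2e-27, and adjusted p = 6.5e-04 with an estimated correlation) and the class I presentation list one of 0.68 (adjusted p = 1.0e-15, and adjusted p = 0.0012 with an estimated correlation). Smooth muscle and pericyte markers, a sign of other cell types in the preparation, had a median of -0.33 with 1 of 10 lower (adjusted p = 0.0053, and adjusted p = 0.021 with an estimated correlation). Calcium handling genes (median -0.24, adjusted p = 0.0053, and adjusted p = 0.52 with an estimated correlation), cardiac transcription factors (-0.25, adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation) and endothelial markers (-0.31, adjusted p = 0.014, and adjusted p = 0.48 with an estimated correlation) were lower too. The first pair of lists lost their calls without CM replicate 3 (adjusted p = 0.14 and 0.20), the transcription factors also without control replicate 1 (0.073), and the endothelial list without control replicate 4 (0.092). Ventricular markers (-0.23, adjusted p = 0.034, and adjusted p = 0.52 with an estimated correlation), fatty acid oxidation (-0.14, adjusted p = 0.026, and adjusted p = 0.72 with an estimated correlation) and cell cycle genes (-0.16, adjusted p = 0.034, and adjusted p = 0.72 with an estimated correlation) passed as well, but not with median scaling (adjusted p = 0.18, 0.098 and 0.071). They did not pass without CM replicate 3 either (0.21, 0.21 and 0.14), nor, for each of them, without several other arrays. The cardiomyocyte genes Nppa and Myh6, at 0.04 (SE 0.06) and -0.05 (SE 0.14), did not pass, and their probes were close to the scanner's maximum. In limma, 289 genes passed, 217 higher and 72 lower, and 165 with only these 8 arrays in the fit.

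After 12 h of CM, Il1b was higher by 6.22 (SE 0.14), at least 28.5-fold, and Csf2, the growth factor GM-CSF, by 5.71 (SE 0.36) (n = 4 per group, adjusted p = 7.6e-22 and 7.1e-12). Mediators that had not passed with PCI now rose, among them Ccl2 by 1.43 (SE 0.22), Cxcl1 by 1.26 (SE 0.16) and Cxcl10 by 4.23 (SE 0.23, at least 6.87-fold). The Cxcl1 probe was close to the scanner's maximum, so its change is compressed. Lcn2 rose by 3.20 (SE 0.36) and Ptges by 3.47 (SE 0.19, at least 6.77-fold). Sprr2d, a cornified envelope protein of a family of near-identical genes whose probes may cross-hybridise, was at 4.84 (SE 0.20, at least 12.1-fold). Fam180a was at -3.71 (SE 0.36, at least 4.83-fold), Tnfsf18 at -2.38 (SE 0.40, at least 2.16-fold), Bmp4 at -1.62 (SE 0.24) and the tight junction gene Cldn15 at -1.82 (SE 0.32). Single markers of other cardiac cell types were lower too: the fibroblast and epicardial transcription factor Tcf21 at -1.52 (SE 0.33) and the endothelial genes Robo4 and Egfl7 at -1.06 (SE 0.21) and -0.84 (SE 0.19).

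Of 23 NF-κB pathway and feedback genes, 12 rose, 0 fell and 11 did not pass the test (15 higher and 0 lower adjusted over the list alone), including the inhibitors Nfkbia at 1.62 (SE 0.33) and Tnfaip3 at 1.97 (SE 0.29) (median 0.83, adjusted p = 3.8e-19, and adjusted p = 0.0056 with an estimated correlation). Of 25 cytokines and chemokines, 20 rose, 0 fell and 5 did not pass the test (22 higher and 0 lower adjusted over the list alone) (median 1.53, adjusted p = 8.8e-49, and adjusted p = 9.7e-05 with an estimated correlation). Of 22 NRF2 and oxidative stress genes, 6 rose, 0 fell and 16 did not pass the test (7 higher and 0 lower adjusted over the list alone), with Slc7a11 at 2.84 (SE 0.22) and the glutathione synthesis gene Gclm at 0.76 (SE 0.15) (median 0.25, adjusted p = 1.5e-07, and adjusted p = 0.001 with an estimated correlation). Of 14 mediator and oxidative enzymes, 7 rose, 0 fell and 7 did not pass the test (9 higher and 0 lower adjusted over the list alone) (median 0.88, adjusted p = 4.1e-13, and adjusted p = 4.4e-04 with an estimated correlation). Of 28 type I interferon-stimulated genes, 26 rose, 0 fell and 2 did not pass the test (26 higher and 0 lower adjusted over the list alone) (median 2.17, adjusted p = 1.0e-71, and adjusted p = 2.4e-04 with an estimated correlation). Smooth muscle and pericyte markers had a median of -0.56, 2 of 10 lower (adjusted p = 0.002, and adjusted p = 0.013 with an estimated correlation). Endothelial markers had one of -0.47, 3 of 14 lower (adjusted p = 2.2e-04, and adjusted p = 0.16 with an estimated correlation). Fibroblast and epicardial markers, at medians of -0.21 (adjusted p = 0.12, and adjusted p = 0.70 with an estimated correlation) and -0.42 (adjusted p = 0.08, and adjusted p = 0.48 with an estimated correlation), did not pass as lists. Sarcomere genes had a median of -0.14 (adjusted p = 0.33, and adjusted p = 0.82 with an estimated correlation). Calcium handling genes were at -0.17, 2 of 22 lower (adjusted p = 0.012, and adjusted p = 0.64 with an estimated correlation), and lost their call without control replicate 1 (adjusted p = 0.086) or CM replicate 3 (0.19). Fatty acid oxidation genes were lower as a list (-0.19, adjusted p = 0.0028, and adjusted p = 0.63 with an estimated correlation), with none of 29 past the test alone. In limma, 360 genes passed, 228 higher and 132 lower. With median scaling in place of quantile normalisation the split was 223 and 79, and with array weights it turned, to 353 and 444. The CM changes at 6 h and 12 h correlated across genes at r = 0.826, and 162 genes were higher and 47 lower at both times (independent lists 5.99 and 1.15).

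**Figure D3:**
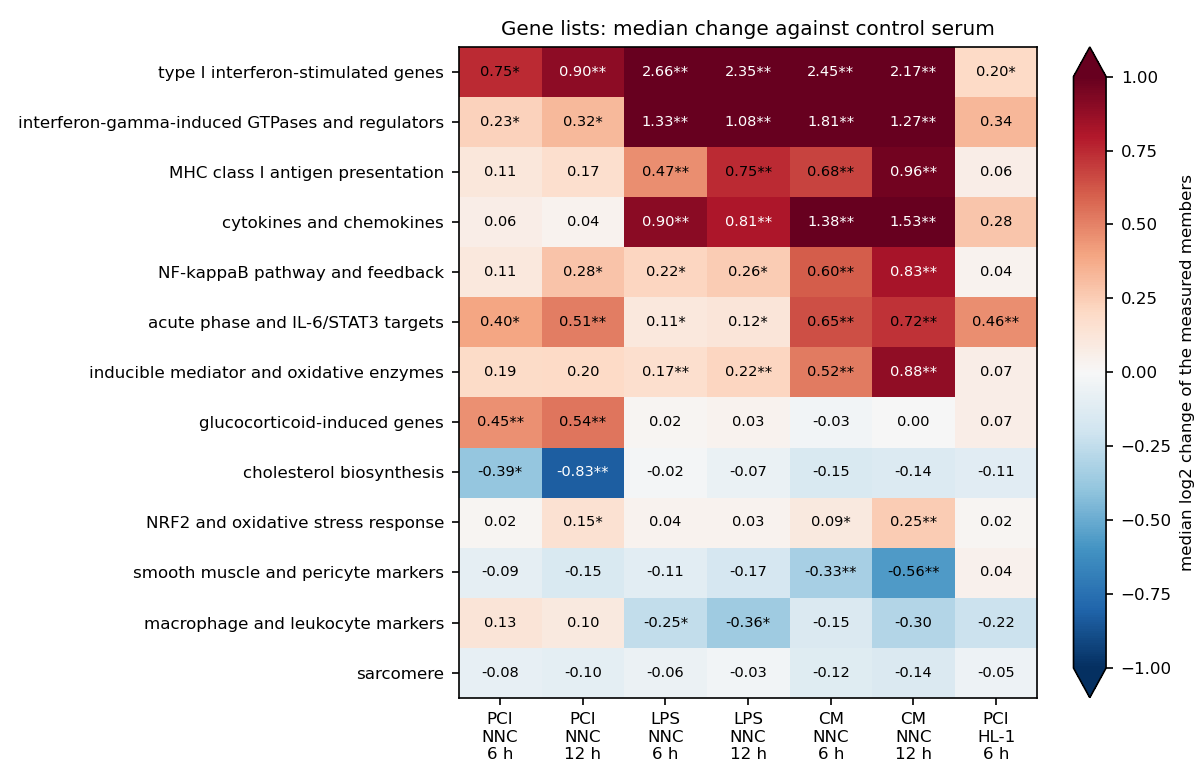
Median log2 change against control serum of the measured members of 13 gene lists (vertical axis) in each comparison (horizontal axis), with 1 star where the list test passed and a pair of stars where it also passed with an estimated correlation. Glucocorticoid-induced genes had medians of 0.45 and 0.54 with PCI in NNC and of 0.02 and 0.03 with LPS.

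The stimuli were then set against each other. With LPS or CM as the reference, Slc10a6 was higher with PCI at 6 h by 4.57 (SE 0.22, at least 11.6-fold) and 3.34 (SE 0.22), and at 12 h by 4.25 (SE 0.23, at least 8.58-fold) and 4.02 (SE 0.22, at least 8.94-fold) (n = 4 per group, 3 for LPS at 12 h). Fkbp5 was higher with PCI than with LPS by 1.56 (SE 0.15) at 6 h and 1.44 (SE 0.16) at 12 h. Serpina3n was higher by 2.42 (SE 0.23) and 2.49 (SE 0.25), and Cdo1, an enzyme of cysteine breakdown, at 12 h by 2.21 (SE 0.29, at least 3.38-fold). In the other direction, Il1b differed by -5.15 (SE 0.14, at least 19.3-fold) at 6 h and -5.42 (SE 0.15, at least 21.4-fold) at 12 h, Rsad2 by -5.83 (SE 0.27) and -3.85 (SE 0.29, at least 11.3-fold), and Cxcl10 at 6 h by -5.80 (SE 0.23, at least 23.4-fold). Against CM at 12 h, Il1b differed by -5.81 (SE 0.14, at least 27.97-fold), Csf2 by -5.37 (SE 0.36) and Ccl5, a chemokine for T cells, by -5.64 (SE 0.75).

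Glucocorticoid-induced genes were higher with PCI than with LPS at 6 h, 6 of 21 past the test (median 0.48, adjusted p = 7.4e-13, and adjusted p = 6.5e-05 with an estimated correlation), and at 12 h, 7 of 21 (median 0.50, adjusted p = 1.2e-11, and adjusted p = 1.5e-04 with an estimated correlation). Against CM their medians were 0.59 at 6 h (adjusted p = 6.8e-07, and adjusted p = 0.0021 with an estimated correlation) and 0.42 at 12 h (adjusted p = 1.4e-06, and adjusted p = 0.0047 with an estimated correlation). Type I interferon-stimulated genes were lower with PCI than with LPS, 23 of 28 at 6 h (median -1.61, adjusted p = 6.9e-86, and adjusted p = 6.5e-05 with an estimated correlation) and 19 at 12 h (median -1.38, adjusted p = 2.8e-58, and adjusted p = 6.2e-04 with an estimated correlation). Cytokines and chemokines were lower with PCI than with LPS at 6 h (median -0.80, adjusted p = 4.0e-31, and adjusted p = 7.1e-04 with an estimated correlation) and than with CM at 12 h (median -1.57, adjusted p = 8.8e-38, and adjusted p = 5.7e-04 with an estimated correlation). Cholesterol biosynthesis genes were lower with PCI than with LPS at 12 h (median -0.60, adjusted p = 1.8e-12, and adjusted p = 0.079 with an estimated correlation). Macrophage and leukocyte markers were higher with PCI than with LPS at 12 h (median 0.43, adjusted p = 3.6e-04, and adjusted p = 0.30 with an estimated correlation). In limma, 190 genes differed between PCI and LPS at 6 h (84 higher, 106 lower) and 183 at 12 h (81 and 102). Between PCI and CM 426 genes differed at 6 h (216 and 210) and 577 at 12 h (323 and 254). With median scaling this last split was 181 and 293. With only the arrays compared in the fit, the PCI against LPS counts were 107 and 76 and the PCI against CM counts 226 and 346.

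CM set against LPS differs both in the cytokines and in the LPS dose, and the arrays cannot part them. With CM, Lcn2 was higher by 2.39 (SE 0.36), Hamp by 1.9 (SE 0.17, at least 1.55-fold), Ptges by 1.32 (SE 0.19) and Tlr2 by 1.43 (SE 0.17) at 6 h (n = 4 per group), while Medag was at -1.19 (SE 0.22). At 12 h, Csf2 was higher with CM by 2.72 (SE 0.39), Ptges by 1.61 (SE 0.21) and Hamp by 1.92 (SE 0.19, at least 1.18-fold) (n = 4 CM and 3 LPS arrays). Cxcl10 did not pass at either time (0.24 (SE 0.23) and 1.07 (SE 0.25)). NF-κB pathway and feedback genes were higher with CM at 6 h, 3 of 23 past the test (median 0.44, adjusted p = 1.7e-16, and adjusted p = 0.024 with an estimated correlation), and at 12 h, 1 (median 0.54, adjusted p = 1.3e-17, and adjusted p = 0.017 with an estimated correlation). Acute phase and IL-6/STAT3 targets were higher at 6 h (median 0.38, adjusted p = 7.7e-19, and adjusted p = 0.021 with an estimated correlation) and 12 h (median 0.51, adjusted p = 6.5e-14, and adjusted p = 0.02 with an estimated correlation). Smooth muscle and pericyte markers were lower at 6 h (median -0.17, adjusted p = 0.0048, and adjusted p = 0.03 with an estimated correlation) and 12 h (median -0.17, adjusted p = 0.0069, and adjusted p = 0.039 with an estimated correlation). In limma, 34 genes differed at 6 h (28 higher, 6 lower) and 25 at 12 h (22 and 3, or 29 and 0 in the deposited log2 table). Each array left out lowered the 6 h count, to between 11 and 22, and the 12 h count was 16 without LPS replicate 1 and 12 without LPS replicate 2. With only the arrays compared in the fit, the counts were 14 and 7, and Hamp lost its call at 12 h.

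Similarity of the responses was measured as the correlation of changes across 8257 genes. The stimuli share control arrays, so each side was given its own 2 of the 4 controls. LPS and CM correlated at r = 0.537 at 6 h and 0.531 at 12 h, PCI and LPS at 0.0147 and 0.0656, and PCI and CM at 0.0593 and 0.0891. With the same controls on both sides, the 6 h values were 0.860, 0.371 and 0.367, where simulated unchanged groups gave 0.50, 0.502 and 0.501. The covariance of LPS and CM at 6 h was 0.125 against 0.0287 simulated, a difference of 0.0959. For PCI and LPS it was 0.0322 against 0.0288 (0.00340), and for PCI and CM 0.0386 against 0.0288 (0.00987). At 12 h these differences were 0.0860, 0.00459 and 0.010. Of the genes higher with LPS at 6 h, 100 were also higher with CM (independent lists 2.68) and 17 with PCI (independent lists 0.976). Part of any excess may come from the shared controls.

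HL-1 cells were given PCI serum for 6 h to compare a cell line with primary cells. Socs3, a feedback inhibitor of cytokine receptor signalling through STAT3, rose by 2.23 (SE 0.16) (n = 4 per group, adjusted p = 4.6e-04). Uts2r, the receptor for the vasoactive peptide urotensin, rose by 1.32 (SE 0.11) and Plppr1 by 1.24 (SE 0.13). Osmr, a receptor subunit for oncostatin M, rose by 1.52 (SE 0.19), the growth factor Csf1 by 1.29 (SE 0.16), Irf9 by 1.08 (SE 0.13) and Parp14, an ADP-ribosyltransferase induced by interferon, by 1.08 (SE 0.14). Of 10 measured acute phase and IL-6/STAT3 targets, 3 rose, 0 fell and 7 did not pass the test (5 higher and 0 lower adjusted over the list alone), with a median of 0.46 (adjusted p = 1.3e-06, and adjusted p = 0.038 with an estimated correlation). Fkbp5 was at 0.21 (SE 0.17), Nppa at -0.05 (SE 0.11) and Cxcl1 at 0.35 (SE 0.19), none past the test. Glucocorticoid-induced genes had a median of 0.07, with 0 of 16 higher (adjusted p = 0.35, and adjusted p = 0.53 with an estimated correlation).

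In limma, 11 of 7409 genes passed in HL-1, 10 higher and 1 lower (8 and 2 with median scaling), and 728 had an unadjusted p under 0.05. This count depended on single arrays. Without PCI replicate 4 it was 284 (78 higher, 206 lower), without PCI replicate 3 it was 3, without control replicate 3 4, without control replicate 4 4, and without PCI replicate 2 7. Socs3, Uts2r and Plppr1 passed with each array left out. Osmr, Csf1, Irf9 and Parp14 lost their calls without PCI replicate 3 (adjusted p = 0.052, 0.062, 0.062 and 0.062). Without control replicate 3 Osmr (0.064), Csf1 (0.063) and Parp14 (0.063) lost them, and without control replicate 4 Osmr (0.068), Irf9 (0.068) and Parp14 (0.068). In HL-1 the replicate numbers paired the arrays, and with the number as a block 29 genes passed. These included Stat3 (1.03 (SE 0.17), adjusted p = 0.062 without and 0.015 with the block) and Per1 (0.94 (SE 0.16), 0.064 and 0.03). Over the alternatives these p ranged from 6.5e-05 to 0.20 for Stat3 and from 0.0023 to 0.28 for Per1. Type I interferon-stimulated genes had a median of 0.20 (adjusted p = 0.02, and adjusted p = 0.39 with an estimated correlation), and the list did not pass with the block (adjusted p = 0.16), without control replicate 1 (0.45) or without PCI replicate 4 (0.34).

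The difference between the responses of the cell models was tested directly. Slc10a6 responded more in NNC than in HL-1, by 4.38 (SE 0.31) (n = 4 arrays in each of the 4 groups, adjusted p = 9.0e-07), as did Usp18 by 2.62 (SE 0.39), Serpina3n by 2.52 (SE 0.26) and Fkbp5 by 1.44 (SE 0.22). Uts2r and Plppr1 responded more in HL-1, with differences of -1.23 (SE 0.16) and -1.31 (SE 0.16). Glucocorticoid-induced genes responded more in NNC (median difference 0.32, adjusted p = 8.4e-06, and adjusted p = 0.046 with an estimated correlation), and so did type I interferon-stimulated genes (median 0.66, adjusted p = 3.4e-12, and adjusted p = 0.22 with an estimated correlation). In limma, 13 of 8480 genes passed, 10 with the larger change in NNC and 3 in HL-1. The count was 36 without HL-1 PCI replicate 4 and 7 without HL-1 control replicate 4. It was 8 without HL-1 control replicate 2 and 8 without HL-1 PCI replicate 3. The PCI changes correlated between the models at r = 0.0894 across 6849 genes, and 3 genes were higher in both, where independent lists would share 0.0623.

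**Figure D4:**
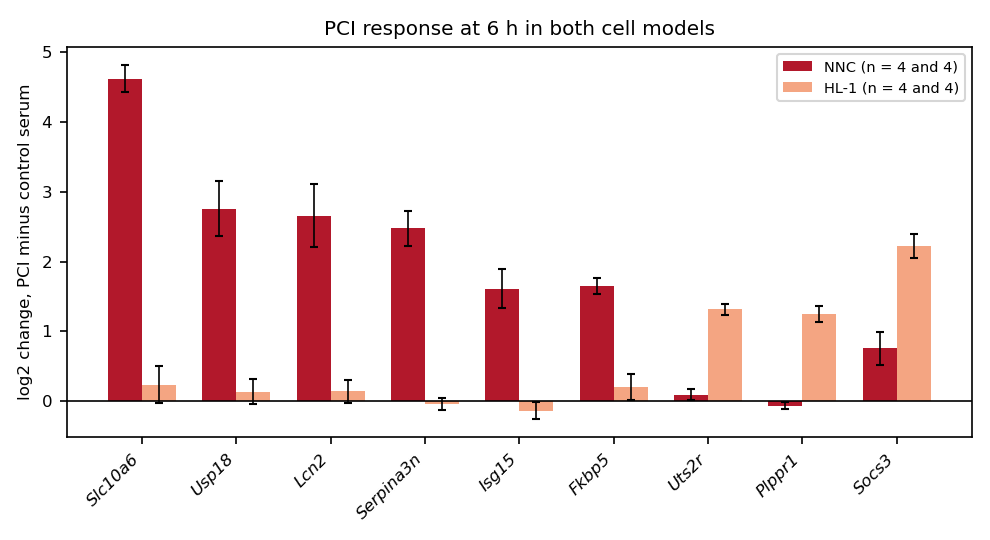
Log2 change of PCI against control serum at 6 h in NNC and HL-1 (bars, difference of means; error bars, SE from the 4 arrays of each group) for 9 named genes whose responses differed between the models. Slc10a6 changed by 4.62 in NNC, and Socs3 by 2.23 in HL-1.

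How far the models differ at baseline was read from control serum at 6 h. Myl2, a ventricular myosin light chain, was at -7.19 (SE 0.14) in HL-1 relative to NNC, and the atrial light chain Myl7 at 4.21 (SE 0.34) (n = 4 per group, adjusted p = 9.1e-17 and 9.1e-09). The matrix proteoglycans Dcn and Bgn were at -9.57 (SE 0.17, at least 270-fold) and -9.51 (SE 0.24, at least 409-fold), the endothelial gene Emcn at -8.98 (SE 0.19, at least 177-fold), the macrophage lysozyme Lyz2 at -7.02 (SE 0.15, at least 46.2-fold) and the epicardial gene Upk1b at -8.22 (SE 0.30, at least 153-fold). The chemokine Ccl7 was at -9.38 (SE 0.22, at least 214-fold), Ccl2 at -8.80 (SE 0.19, at least 150-fold) and Il6 at -6.93 (SE 0.27, at least 49.3-fold). Higher in HL-1 were the hormone receptor Amhr2 at 7.41 (SE 0.20), the developmental transcription factor Otx1 at 6.64 (SE 0.16, at least 37.1-fold), and the cell cycle genes Ccna2 at 4.10 (SE 0.18, at least 6.22-fold) and Mcm2 at 3.62 (SE 0.19). The D-type cyclins Ccnd1 and Ccnd2 went the other way, at -6.15 (SE 0.27) and -8.52 (SE 0.13, at least 121-fold). Of 18 TGF-β and YAP targets, 0 were higher and 17 lower in HL-1 (median -2.77, adjusted p = 2.6e-07, and adjusted p = 0.012 with an estimated correlation).

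Other lists differed by the preset test and not with an estimated correlation. Of 34 extracellular matrix genes 32 were lower (median -4.55, adjusted p = 3.2e-15, and adjusted p = 0.054 with an estimated correlation), of 19 cytokines and chemokines 19 (median -4.45, adjusted p = 8.5e-10, and adjusted p = 0.071 with an estimated correlation), and of 17 macrophage and leukocyte markers 14 (median -3.44, adjusted p = 2.6e-06, and adjusted p = 0.071 with an estimated correlation). Of 34 cell cycle genes 32 were higher (median 3.03, adjusted p = 1.5e-09, and adjusted p = 0.12 with an estimated correlation). Fibroblast markers had a median of -4.19 (adjusted p = 2.6e-07, and adjusted p = 0.071 with an estimated correlation), endothelial markers -3.45 (adjusted p = 8.0e-06, and adjusted p = 0.084 with an estimated correlation), epicardial markers -3.77 (adjusted p = 8.2e-06, and adjusted p = 0.071 with an estimated correlation) and ventricular markers -2.50 (adjusted p = 1.9e-05, and adjusted p = 0.054 with an estimated correlation). The signals of Myl2, Myl7, Nppa and Myh6 came near the scanner's maximum. In limma, 6098 of 8480 genes differed, 3067 higher and 3031 lower in HL-1. The scaling set this balance: the split was 4193 and 2176 in the deposited log2 table and 3782 and 2348 with median scaling, where the median of all genes shifted by 0.291 and 0.287. Changes between the models are therefore relative to the typical gene, and cell model and any batch of cultures or arrays cannot be told apart here.

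Time in control serum is the background for the 12 h results. Between 6 h and 12 h Csf2 fell, at -3.51 (SE 0.36) relative to 6 h (n = 4 per group, adjusted p = 2.1e-06), as did the neutrophil chemokine Cxcl2 at -2.32 (SE 0.30), Ch25h, which makes 25-hydroxycholesterol, at -2.11 (SE 0.27), the cytokine Lif at -1.88 (SE 0.27) and the endothelial selectin Sele at -1.82 (SE 0.19). Lcn2 rose by 1.83 (SE 0.36) and Timeless, a replication and clock protein, by 1.60 (SE 0.34). Of 21 immediate early genes, 0 rose, 4 fell and 17 did not pass the test (0 higher and 12 lower adjusted over the list alone), with Egr2 at -1.47 (SE 0.19) (median -0.57, adjusted p = 1.2e-12, and adjusted p = 0.0034 with an estimated correlation). Of 25 cytokines and chemokines, 1 rose, 6 fell and 18 did not pass the test (2 higher and 9 lower adjusted over the list alone) (median -0.28, adjusted p = 1.3e-05, and adjusted p = 0.29 with an estimated correlation). NF-κB pathway genes had a median of -0.46, with Nfkbiz at -0.92 (SE 0.13) (adjusted p = 3.4e-09, and adjusted p = 0.15 with an estimated correlation). In limma, 257 genes differed, 154 higher and 103 lower, and with median scaling 109, 48 and 61. The count was 98 without 6 h replicate 3, and 164, 129 and 135 without 12 h replicates 1, 2 and 3. Arrays of the same stimulus and number deviated together at both times, and with that culture as a block, an alternative chosen after seeing the data, 1496 genes differed, and 401 with the number alone as a block. With only these 8 arrays in the fit, 14 passed, and Lif and Timeless lost their calls.

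Whether responses changed between 6 h and 12 h was tested as the difference of the responses. For LPS, the response of Cxcl10 was smaller at 12 h, with a difference of -2.51 (SE 0.34), and so was that of the lymphocyte activation gene Cd69 at -2.44 (SE 0.34) (n = 4 arrays per group, 3 for LPS at 12 h, adjusted p = 6.7e-04 and 6.7e-04). For CM, Cd69 differed by -2.18 (SE 0.33) and Cmpk2, an interferon-induced nucleotide kinase, by -2.30 (SE 0.37). Type I interferon-stimulated genes had a median difference of -0.26 for LPS (adjusted p = 6.1e-08, and adjusted p = 1.00 with an estimated correlation) and -0.38 for CM (adjusted p = 4.2e-10, and adjusted p = 0.38 with an estimated correlation). For PCI, cholesterol biosynthesis genes had a median difference of -0.57 (adjusted p = 4.7e-08, and adjusted p = 0.97 with an estimated correlation), with Msmo1 at -0.71 (SE 0.30) (adjusted p = 1.00, or 0.005 with culture as a block). In limma, 0 genes differed for PCI, with 141 at an unadjusted p under 0.05. For LPS 7 differed (1 higher and 6 lower at 12 h) and for CM 9 (2 and 7). With culture as a block the counts were 4, 22 and 55. Split by direction, the LPS count was 0 higher and 5 lower in the deposited log2 table and without background correction, 0 and 4 with median scaling, and the CM count 2 and 3 with median scaling. Single arrays moved these small counts. For LPS, 2 genes passed without control replicate 3 or 4 at 6 h, control replicate 3 at 12 h, LPS replicate 1 at 6 h or LPS replicate 2 at 12 h, 3 without LPS replicate 3 or control replicate 4 at 12 h, and 4 without control replicate 2 at 6 h or replicate 1 of either group at 12 h. For CM, 2 passed without CM replicate 1 at 12 h or without CM replicate 2 or control replicate 4 at 6 h, 3 without CM replicate 2 or control replicate 3 at 12 h, 4 without control replicate 1 at 12 h, 5 without control replicate 4 at 12 h, and 6 without CM replicate 1 or 4 at 6 h.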

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

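The counts over other splits of the arrays and the test of whether NNC genes were detected in HL-1 were planned; the tests of cell preparations with cultures dealt out again, cardiomyocyte share, array quality, single arrays, exchanged labels, the spread of the NNC fit, LPS in the serum and a steroid in the serum were chosen only after the result was seen.

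Of 141 groups of 4 arrays examined for values far from the other 3, 12 held such a value, and chance gives about 1 in 20. Below, the ratio is the gap to the nearest array divided by the range of the group. Cd14 was low on replicate 1 of NNC in control serum at 6 h (7.63, others 8.14 to 8.20, ratio 0.893). With PCI at 6 h, Cd14 was high on replicate 1 (8.84, others 8.61 to 8.62, ratio 0.961). Nppb was low on PCI replicate 2 at 6 h (15.16, others 15.71 to 15.79, ratio 0.876), and so was Atp2a2 (15.82, others 15.85 to 15.86, ratio 0.854). Gbp2 was high on CM replicate 3 at 6 h (12.82, others 12.08 to 12.14, ratio 0.913). Icam1 was high on LPS replicate 1 at 6 h (13.66, others 12.76 to 12.85, ratio 0.895). Myh6 was low on PCI replicate 2 at 12 h (15.18, others 15.66 to 15.71, ratio 0.907). At 12 h with CM, Il6 was high on replicate 1 (13.98, others 12.52 to 12.67, ratio 0.896) and Nfkbia on replicate 3 (11.83, others 10.70 to 10.87, ratio 0.850). Nppb was low on HL-1 control replicate 1 (9.65, others 10.23 to 10.30, ratio 0.898). Among the control arrays at 12 h, replicate 4 had 42.1 % of probes detected (others 39.1 % to 39.5 %, ratio 0.862) and replicate 3 a median signal of 165.2 (others 194.7 to 198.3, ratio 0.891).

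The response to PCI differed between NNC and HL-1 in a test of the difference itself for 13 genes. Named ones were Slc10a6 (4.38), Usp18 (2.62), Lcn2 (2.52), Serpina3n (2.52), Isg15 (1.75), Fkbp5 (1.44), Socs3 (-1.47), Plppr1 (-1.31) and Uts2r (-1.23). Of these, Isg15 lost its call without HL-1 control replicate 4 (adjusted p = 0.053). Lcn2 did without any of 6 arrays (highest 0.073, without HL-1 control replicate 2), and Socs3 without any of 11 (highest 0.13, without HL-1 PCI replicate 3). With the replicate block Isg15 was at 0.067 and Socs3 at 0.093. Lists that differed were glucocorticoid-induced genes (median 0.32), type I interferon-stimulated genes (0.66) and interferon-gamma-induced GTPases (0.48). With an estimated correlation only the first passed. The last had an adjusted p = 0.0014, 0.84 with that correlation and 0.051 without NNC control replicate 3.

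Between 6 h and 12 h the PCI response differed in cholesterol biosynthesis genes (median -0.57), but not with an estimated correlation. The LPS response differed in the interferon-stimulated (-0.26) and GTPase lists (-0.25, adjusted p = 1.1e-06), but not with an estimated correlation (GTPases 0.89). It also differed in 7 genes, Cd14 (0.97), Cxcl10 (-2.51), Cd69 (-2.44), Cmpk2 (-2.15), Rsad2 (-2.10), Gbp5 (-1.77) and Ifit2 (-1.28). All of these genes except Cxcl10 and Cd69 lost their calls without several single arrays, at up to 0.11 for Cmpk2 and 0.11 for Rsad2 (without LPS replicate 3 at 12 h), 0.21 for Cd14 (same array), 0.32 for Gbp5 (without LPS replicate 2 at 12 h) and 0.16 for Ifit2 (without LPS replicate 1 at 12 h). With the replicate block, Rsad2 and Gbp5 were at 0.057 and Cd14 at 0.083.

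The CM response differed in 9 genes, among them Csf2 (2.75), Cd14 (0.99), Cmpk2 (-2.30), Cd69 (-2.18), Rsad2 (-2.05), Gbp5 (-1.82), Cxcl10 (-1.68) and Ifit2 (-1.25). All of these except Cd69 and Cmpk2 lost their calls without CM replicate 1 at 12 h, at adjusted p = 0.07 for Csf2 to 0.10 for Cxcl10, and without several other arrays. Its lists were NF-κB pathway genes (0.26), type I interferon-stimulated genes (-0.38), GTPases (-0.35), mediator enzymes (0.24), NRF2 genes (0.25) and the unfolded protein response (0.22). With an estimated correlation none of them passed (adjusted p = 0.96 for NF-κB, 0.059 for NRF2 and 0.38 for the other 4). Without control replicate 4 at 6 h, the NF-κB (0.17), mediator enzyme (0.083) and unfolded protein response lists (0.083) lost their calls, as they did without CM replicate 2 at 6 h or CM replicate 3 at 12 h and, for each of them, without 1 or more other arrays.

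A first pattern concerns NNC cultures of the same group: in 4 of them (control 4, PCI 2, CM 3 and LPS 1), sarcomere genes lay at -0.57 to -0.45 relative to their group at both times, while epicardial markers lay at 0.24 to 0.41 and macrophage markers at -0.05 to 0.14; the first component of these deviations held 40.0 % of the variance. Whether a lower cardiomyocyte share raised all other cell types alike is not decided by the gap of 0.0930 between epicardial and macrophage ranges. That pair was picked as furthest apart among other cell types, and the offset shrinks changes of dim genes. The other lists were endothelial (0.18 to 0.35), fibroblast (0.08 to 0.36) and smooth muscle markers (-0.05 to 0.15). A lower cardiomyocyte share with more epicardial, endothelial or fibroblast cells stays open. Poorer arrays are argued against, since the culture had the lowest share of detected probes in 0 of 4 stimuli. The same cell preparations in every stimulus remain a candidate explanation for the pair of cultures highest on the first component of each stimulus, since in 4 of 4 stimuli the second of the pair (control 2, PCI 3, LPS 4, CM 1) was highest in cell cycle genes, at 0.27 to 0.48. For all cultures, shared preparations behind reordered replicate numbers cannot be told apart from chance matches. The best matches agreed in 1 of 4 sets of 3 stimuli (control, PCI and LPS). Their matches led the next by 0.113 or more, those with CM by 0.0203 or less. Cultures dealt out again keep any shared preparations, so 22 of 100 dealings as good or better (real mean r = 0.473) decide nothing. No match was used as a block.

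A second pattern is the low number of genes past the test for PCI in HL-1, 11, beside 94 in NNC. Lack of detection is argued against, since 73 of the 94 genes were tested in HL-1. A single array that widens the spread remains a candidate explanation, as 284 genes passed without HL-1 PCI replicate 4, and so does the number of arrays behind the spread, as 12 genes passed in NNC with the spread taken from its own 8 arrays, both on the 7616 genes detected there and on the 8257 of the full fit. An exchange of the labels of HL-1 PCI replicate 4 and control replicate 1 is argued against: over the 73 genes, in the direction of NNC, PCI replicate 4 lay 0.0635 above the highest other control in the mean and control replicate 1 lay 0.164 below the lowest other PCI array (SD within groups 0.0191), although the medians of PCI replicate 4 and that control were close (0.00471 and -0.0103) and over 628 genes called without both arrays PCI replicate 4 lay at a median of 0.0402 (SD 0.419) and control replicate 1 at 0.534 (SD 0.351) between the other controls (0) and PCI arrays (1), which goes part of the way with an exchange. A difference between the cell models stays open as well, since 13 genes differed in the direct test, and it cannot be parted from a batch of cultures.

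The third pattern is the PCI response of NNC, with glucocorticoid-induced and interferon-stimulated genes and without the cytokines that LPS raised. LPS in the serum is argued against for the glucocorticoid-induced genes, whose whole list was higher with PCI than LPS. The 6 chosen by their PCI call at 6 h had medians of 1.37 with PCI and 0.065 with LPS (SD 0.55). For the interferon-stimulated genes LPS cannot be told apart from other causes. The 9 cytokine genes called with LPS had a median of 0.19 with PCI (SD 0.56). Only 1 dose of LPS was given alone, so how both kinds scale at a lower dose is not known. A steroid in the serum that acts on both models cannot be told apart from other causes, because 5 of the glucocorticoid-induced genes had a median of 0.21 in HL-1 (SD 0.70) and 1.09 in NNC. Interferons and cytokines in infectious serum remain an untested hypothesis, and serum with these factors blocked would test it.

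Other splits of the same arrays into groups of the same sizes were counted. The smallest share that 35 splits can give is 1 of 35, with no allowance for the number of comparisons. Chance is therefore made unlikely, not excluded, where a single split, the real one, gave as many genes. This held for 1 of the 35 splits in each of the following, with the real count and then the highest other: in NNC at 6 h, PCI (94, 1), LPS (105, 0) and CM (289, 1) relative to control; at 12 h, PCI (118, 0), LPS (92, 64) and CM (360, 1); CM relative to LPS at 6 h (34, 0) and 12 h (25, 9); PCI relative to LPS at 6 h (190, 1) and 12 h (183, 84); PCI relative to CM at 6 h (426, 1) and 12 h (577, 2); and HL-1 relative to NNC (6098, 0). The 64 and 84 came from splits that moved 1 array of the real groups. For the difference between the models, 1 of 100 draws of the deviations, the real one, gave as many (13, highest other 3). These draws ignored that the numbers pair the HL-1 arrays.

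For PCI in HL-1, 2 of the 35 splits gave as many as the real 11, so this count does not make chance unlikely. The other split, with PCI replicates 1 to 3 and control replicate 1 on 1 side, gave 924, which points to a structure of the samples. That split exchanges PCI replicate 4 and control replicate 1, and the count was 284 without the first of them and 13 without the second. Of the 8 splits that part all 4 numbered pairs, too few for a share under 0.05, 1 gave as many, the real one, and the highest other gave 0. For the responses at 12 h relative to 6 h, 2 of 100 draws of the deviations gave as many for LPS (7, highest other 1922) and 2 for CM (9, highest other 109), the real order included. These draws ignored the pairing of the times by number. The high values again point to a structure of the samples, whose source was not tested. For PCI, 100 of 100 gave as many as the real 0 of limma (141 at an unadjusted p under 0.05, highest other 1213). For control at 12 h relative to 6 h, 1 of the 35 splits gave as many (257, highest other 0), but the numbers pair these arrays, and the 8 splits that part all 4 pairs are too few for a share under 0.05 (1 gave as many, highest other 0).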

How the results depend on the processing

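Removing the apart NNC cultures and blocking by NNC culture were chosen after seeing the data. All others were planned. No gene or list value reversed. Of 309 gene values followed over the alternatives, 274 were past the test and 197 of these passed under every alternative run. Over all alternatives 5756 gene values kept their side of the threshold, 462 lost it and 27 gained it. Of the 187 gene list results, 3571 alternative values kept their call and 379 lost it. The estimated correlation left 73 of the 187 list calls. Array weights, which are unequal, mostly raised the counts. The arrays compared alone lowered them, with the spread from fewer arrays and fewer genes tested. For PCI in NNC at 6 h the count stayed at 12 with all 8257 genes kept, a fit also chosen after seeing the data. For the other settings the cause was not tested. The weight of probe detection beside array numbers was not measured.

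With each array left out in turn, the number of genes ranged from 3 to 284 for PCI in HL-1, 7 to 36 for the difference between the models, 2 to 6 and 2 to 9 for the LPS and CM responses at 12 h relative to 6 h, 11 to 22 and 12 to 23 for CM relative to LPS at 6 h and 12 h, and 98 to 259 for control at 12 h relative to 6 h. For PCI, LPS and CM relative to control in NNC it was 63 to 89, 90 to 119 and 223 to 280 at 6 h and 81 to 119, 74 to 91 and 278 to 343 at 12 h.

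Array weights gave 285 genes for PCI, 275 for LPS and 797 for CM relative to control in NNC at 12 h, 553 for PCI in HL-1, 104 for the difference between the models, 13 for LPS between the times, 78 and 530 for CM relative to LPS, 299 and 738 for PCI relative to LPS, 657 and 1036 for PCI relative to CM, and 472 for control between the times. With the arrays compared alone in the fit, the counts were 12 for PCI and 165 for CM at 6 h, 39 for PCI at 12 h, 4 and 4 for LPS and CM between the times, 14 and 7 for CM relative to LPS, 107 and 76 for PCI relative to LPS, 226 and 346 for PCI relative to CM, and 14 for control between the times. All 39 arrays in the fit gave 110 for PCI in HL-1 and 37 for the difference between the models.

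A change of at least 2-fold as well left 36 and 50 genes for PCI and 157 and 180 for CM in NNC, 19 for CM relative to LPS at 6 h, 106 and 102 for PCI relative to LPS, 179 and 215 for PCI relative to CM, 3627 between the models and 53 for control between the times. Median scaling gave 4 and 5 for LPS and CM between the times, 17 for CM relative to LPS at 6 h and 109 for control between the times. Without a filter on dim probes, 3 genes passed for LPS between the times and 20 for CM relative to LPS at 6 h. With detection on at least 0.5 of the arrays, 0 passed in limma for LPS between the times (119 at an unadjusted p under 0.05 in the unchanged analysis) and 16 for CM relative to LPS at 12 h. Without the apart cultures, CM relative to LPS at 12 h had 47. With the same controls on both sides, PCI and LPS correlated at 0.371 and 0.376 at 6 h and 12 h, PCI and CM at 0.367 and 0.338, and LPS and CM at 0.860 and 0.817.

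The larger direction of a count turned in some settings (higher, then lower). With median scaling PCI relative to CM at 12 h went from 323 and 254 to 181 and 293, and control between the times from 154 and 103 to 48 and 61. The latter also turned with its own arrays alone (3 and 11) and without 6 h replicate 3 (40 and 58). Array weights turned CM in NNC at 12 h (228 and 132 to 353 and 444), CM relative to LPS at 12 h (22 and 3 to 260 and 270), PCI relative to LPS at 12 h (81 and 102 to 372 and 366) and PCI in HL-1 (10 and 1 to 184 and 369). PCI in HL-1 also turned with all 39 arrays in the fit (47 and 63) and without PCI replicate 4 (78 and 206). The near balance of HL-1 relative to NNC (3067 and 3031) turned without a filter on dim probes (3347 and 3429), with all 39 arrays (3145 and 3277) and without HL-1 control replicate 2 (2912 and 2921), and that of PCI relative to CM at 6 h (216 and 210) under many, among them 244 and 295 without the apart cultures.

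The replicate block gave 29 genes for PCI in HL-1, 4 for LPS between the times and 401 for control between the times. In NNC, arrays of different stimuli share only a number: 18 of 45 correlated best with their own number. With culture as the replicate block, the PCI, LPS and CM responses between the times had 4, 22 and 55 genes and control between the times 1496. Where numbers pair the arrays, the block moved no other count by over 1.5 times and changed no call of a gene or list in the text besides those printed with their blocked p. The slide block was not run.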

Other observations

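Receptors and adaptors for LPS and cytokines moved little as a group. With LPS at 6 h, 2 of 15 passed, Cd14 and Tlr2 (median 0.09, adjusted p = 7.3e-05, 0.04 with an estimated correlation). With CM it was 4 at 6 h (median 0.12, adjusted p = 1.8e-05, 0.021 with an estimated correlation). At 12 h it was 2 (median 0.15, adjusted p = 1.8e-05, 0.017 with an estimated correlation). Leukocyte adhesion molecules went both ways with CM at 12 h, 4 of 13 higher and 1 lower (median 0.40, adjusted p = 0.0059, 0.31 with an estimated correlation). Apoptosis regulators had 5 of 21 higher with CM at 6 h (median 0.11, adjusted p = 3.1e-04, 0.099 with an estimated correlation). With LPS they had 2 (median 0.06, adjusted p = 2.3e-04, 0.14 with an estimated correlation). NRF2 and oxidative stress genes were higher with CM than with LPS at 12 h (median 0.26, 1 of 22 past the test, adjusted p = 5.9e-09, 0.0014 with an estimated correlation).

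Genes of fatty acid oxidation, the main fuel pathway of adult heart muscle, were higher with PCI than with CM at 12 h, 4 of 29 past the test (median 0.22, adjusted p = 3.6e-05, and adjusted p = 0.46 with an estimated correlation). With CM relative to control at 12 h their median was -0.19, with none past the test in limma (adjusted p = 0.0028, 0.63 with an estimated correlation). Sarcomere genes were lower in HL-1 than in NNC, 18 of 26, with 3 higher (median -1.64, adjusted p = 4.3e-04, 0.35 with an estimated correlation). Leukocyte adhesion molecules were lower in HL-1 as well, 11 of 13 (median -2.16, adjusted p = 1.9e-04, 0.11 with an estimated correlation). Lists of the circadian clock, glycolysis, oxidative phosphorylation and heat shock proteins passed in no comparison. MHC class II had no call either, but in each group 2 of its 12 members were detected on all arrays and 8 to 10 on none. Lists with fewer than 5 measured members were not tested, so nothing can be said of MHC class II here.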
